A study of Macaca fascicularis with 10 samples.

How the data were processed

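RNA of 10 samples of Macaca fascicularis had been hybridised to Affymetrix Rhesus Macaque arrays, with 1 array per sample. Per the labels, stem cells were grown on feeder cells with the kinase inhibitors Y27635 and Thiazovivin, RNA was extracted with TRIZOL and labelled with the GeneChip 3' IVT Express kit. The feeder species is not given in the sources used here. The deposited values are linear signal intensity, which the authors made with MAS5, whose release is not given in the sources used here. The mean of each array without its highest and lowest 2% of probe sets was the same whole number on all 10 arrays after rounding, so arrays had been scaled to a common mean, with no other normalization between arrays found. The table held no detection calls, so the signal of a probe set that is not expressed is unknown. Array medians ran from 76.8 to 133.

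Of 52865 probe sets, 158 control probe sets were left out and 34139 above their array's median signal on at least 2 arrays were tested. Gene symbols came from the probe annotation supplied with the data. 24956 probe sets had 1 symbol, 361 had several and 27390 had none. A gene was represented by its probe set of highest mean log2 signal among those with that symbol alone, which gave 11639 genes, 4859 of them with 2 or more tested probe sets. Chromosomes came from the assembly T2T-MFA8v1.1 (89.0% of the annotation's symbols matched), which placed 10548 of the genes tested. LIN28A, XIST and MEG3 had no probe set named in the annotation used here.

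Groups followed the labels: PG-haESC (5 arrays), ICSI ESC (3 arrays) and fibroblast (2 arrays). The titles name 1 line, MPH1, for arrays with the codes M1 and M2, and the conflict was left to the alternatives. Each of the 3 pairs of groups was compared with limma 3.58.1 in R 4.3.3 on log2 signal, in a single model of all 10 arrays with group means, cell line as a random block (estimated correlation 0.29), a variance trend with intensity and two-sided tests. Residual and prior degrees of freedom were 7 and 5.37. P-values were adjusted by the Benjamini-Hochberg method over all probe sets tested, and an adjusted p under 0.05 was called. Where every array of the dimmer group lay at or under its array's median signal, the fold was taken with each signal of that group raised to its array's median and written as a lower bound. The 24 gene lists were tested with camera, a test of a list against all other genes, with a preset correlation between genes of 0.01, adjusted over lists, and again with an estimated correlation. The X-linked list was tested against genes placed on autosomes alone. The Y-linked list had 1 measured gene and no list test. A difference in the median X-linked level per array was tested by exact permutation. Intervals of chromosome medians are bootstrap 95% intervals over genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

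Tests, lists, filter, most alternatives and the rule for named genes were set before the data were examined. The rule took the 10 genes higher and the 10 lower with the largest fold between PG-haESCs and ICSI ESCs among genes called whose ranges did not overlap, 6 and 6 for each fibroblast comparison, up to 4 members of each list with the smallest p, and POU5F1, NANOG, SOX2, LIN28A, XIST, COL1A1, SNRPN, PEG3, MEST, H19 and MEG3 where measured. A direction short of called genes was filled by smallest p. The alternatives were other handling of line and description code, an offset of 32 before log2, quantile normalization, centring on array medians, and no filter or a 75th percentile filter. Further ones were variance without trend or robust, passage as a covariate, the mean of all probe sets of a gene and only the groups compared. The remaining alternatives were a 2-fold threshold, an estimated correlation and leaving out each array. Those chosen after seeing the data were leaving out the 2 arrays with the highest spike-in control signals, setting signals below the array median to it, and the fibroblast list score as a covariate. Lists of epidermal, melanocyte, endothelial, adipocyte, leukocyte and ATF4 target genes were also made after the data had been seen.

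The method was tested on simulated data with 34139 probe sets of which 200 were changed at a line correlation of 0.3. Between PG-haESCs and ICSI ESCs it recovered 9% to 15% of 2-fold and 42% to 46% of 4-fold changes, with 5 false calls. The fibroblast comparisons recovered 2% to 8% of 2-fold and 30% to 44% of 4-fold changes, with 0 to 4 false calls. In the real fibroblast comparisons 11275 and 11150 probe sets were called, far more than were changed in the simulation. The adjustment of p-values depends on that share, so the simulated recovery does not describe the sensitivity of the real fibroblast comparisons.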

Results

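Gene expression was measured on 10 Affymetrix Rhesus Macaque arrays hybridised with RNA of cynomolgus monkey (Macaca fascicularis) cells. Parthenogenetic haploid embryonic stem cells (PG-haESCs), derived without a sperm genome and labelled haploid, gave 5 arrays. They came from a line named MPH1 (4 arrays, passages 7 to 11, under codes M1 and M2) and a line named MPH2 (1 array, passage 4). Embryonic stem cells (ESCs) from embryos made by intracytoplasmic sperm injection (ICSI), labelled diploid, gave 3 arrays of 3 lines at passages 4 and 12. Cells labelled female somatic fibroblasts gave 2 arrays, at passages 14 and 15 under 1 line name and 1 code. The ICSI ESCs and the fibroblasts were the study's controls. Nothing in the labels ties arrays of 1 line to separate cultures. The p-values of single genes thus measure the spread between these samples, part of which may be technical. The p-value of a gene list sets its genes against other genes and does not measure the spread between samples or lines. The number of arrays limits the precision of every value.

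PG-haESC and ICSI ESC arrays had similar profiles over the 34139 probe sets tested. Across probe sets, which are not independent replicates, the median Pearson r was 0.893 between the groups (15 pairs), 0.904 within PG-haESC and 0.881 within ICSI ESC. The 2 arrays labelled fibroblast correlated at 0.945 with each other, and at a median of 0.643 with PG-haESC and 0.649 with ICSI ESC arrays.

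The comparison of PG-haESCs with ICSI ESCs asked how far haploid ESCs of maternal origin alone differ from ESCs of a fertilised embryo. The strongest difference was the near loss of SNRPN, an imprinted gene that mammals transcribe from the paternal allele. Its signal averaged 380 in PG-haESCs (geometric mean, SD 0.85 log2, n = 5) and 21785 in ICSI ESCs (SD 0.26 log2, n = 3), 56.0-fold lower in PG-haESCs. The log2 change was -5.81 ± 0.49 (SE, limma, adjusted p = 0.0013), and both SNRPN probe sets passed the test. Log2 changes are estimates that weight arrays by line, so they can differ from ratios of the printed means. Genes on the X chromosome were higher in PG-haESCs as a group. Among single genes, the largest rise was that of PCDH8, a protocadherin of cell adhesion, which averaged 6387 (SD 1.2 log2) against 174 (SD 0.45 log2), 31.6-fold higher (log2 change 4.98 ± 0.63, adjusted p = 0.0080).

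Of the probe sets tested, 154 differed between PG-haESCs and ICSI ESCs at an adjusted p under 0.05, 125 higher and 29 lower in PG-haESCs, and 130 of them by at least 2-fold. At an unadjusted p under 0.05 the number was 2515. By gene, 59 rose and 8 fell. Of those that rose, 36 were placed on the X chromosome, 12 on autosomes and 11 had no placement. A gene not marked as X-linked here may thus lack a placement. After PCDH8, the largest rises were those of VTCN1, an immune checkpoint ligand (7.72-fold, adjusted p = 0.048), ABCA8, a membrane transporter (3.90-fold, adjusted p = 0.039), and the X-linked FHL1, a LIM domain protein (3.78-fold, adjusted p = 0.048). With the mean of all probe sets of a gene, ABCA8, with 1 of its 4 probe sets past the threshold, had a log2 change of 0.65 rather than 1.96 and did not pass (adjusted p = 0.87, and 0.0023 to 0.87 over all alternatives), and FHL1 had 1.27 rather than 1.92. LOC714113 (3.74-fold), the X-linked KLHL13 (3.54-fold) and SEPTIN6 (3.40-fold), NAP1L2 (3.29-fold), the X-linked glycosylation gene ALG13 (3.28-fold) and the protease gene KLK7 (3.2-fold) followed, with adjusted p from 0.0055 to 0.039. Below SNRPN, the genes that fell were ZNF385B (4.30-fold), the amino acid transporter gene SLC6A15 (3.13-fold), DDIT4 (2.95-fold), DDIT3 (2.64-fold), CHAC1 (2.35-fold), C1H1orf115 (2.25-fold) and PDLIM1 (2.25-fold), with adjusted p from 0.0069 to 0.048. DDIT3 encodes the stress-response transcription factor CHOP, DDIT4 an inhibitor of mTORC1 and CHAC1 an enzyme of glutathione breakdown. HDDC2 (log2 change -0.94, adjusted p = 0.052) and HERPUD1 (-0.94, adjusted p = 0.054), the next by p, did not pass. For each of these genes all 5 PG-haESC arrays lay on 1 side of all 3 ICSI ESC arrays. This was part of the rule that chose the genes past the threshold, but not of the fill by p that gave HDDC2 and HERPUD1.

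The number of calls between PG-haESCs and ICSI ESCs rested on single arrays. It was 8 without ICSI ESC array 3, 41 without ICSI ESC array 2 and 395 without ICSI ESC array 1. Leaving out PG-haESC array 1, 2, 3, 4 or 5 gave 42, 101, 40, 85 or 192. Without array 5, the only array of line MPH2, 105 of the 154 calls were kept. Leaving out either fibroblast array also moved the number, since those arrays enter the shared estimate of spread. Taking arrays as independent samples gave 475. Averaging the arrays of each line first left 9, all lower. The number was 20 when averaged per description code and 13 without an intensity trend in the variance. With arrays centred on their medians it was 30, of which 43.3% were higher against 81.2% above. SNRPN passed under all 27 alternatives, and each of the other 20 named genes past the threshold lost its call under 2 to 17 of the 27 without changing direction.

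**Figure D1:**
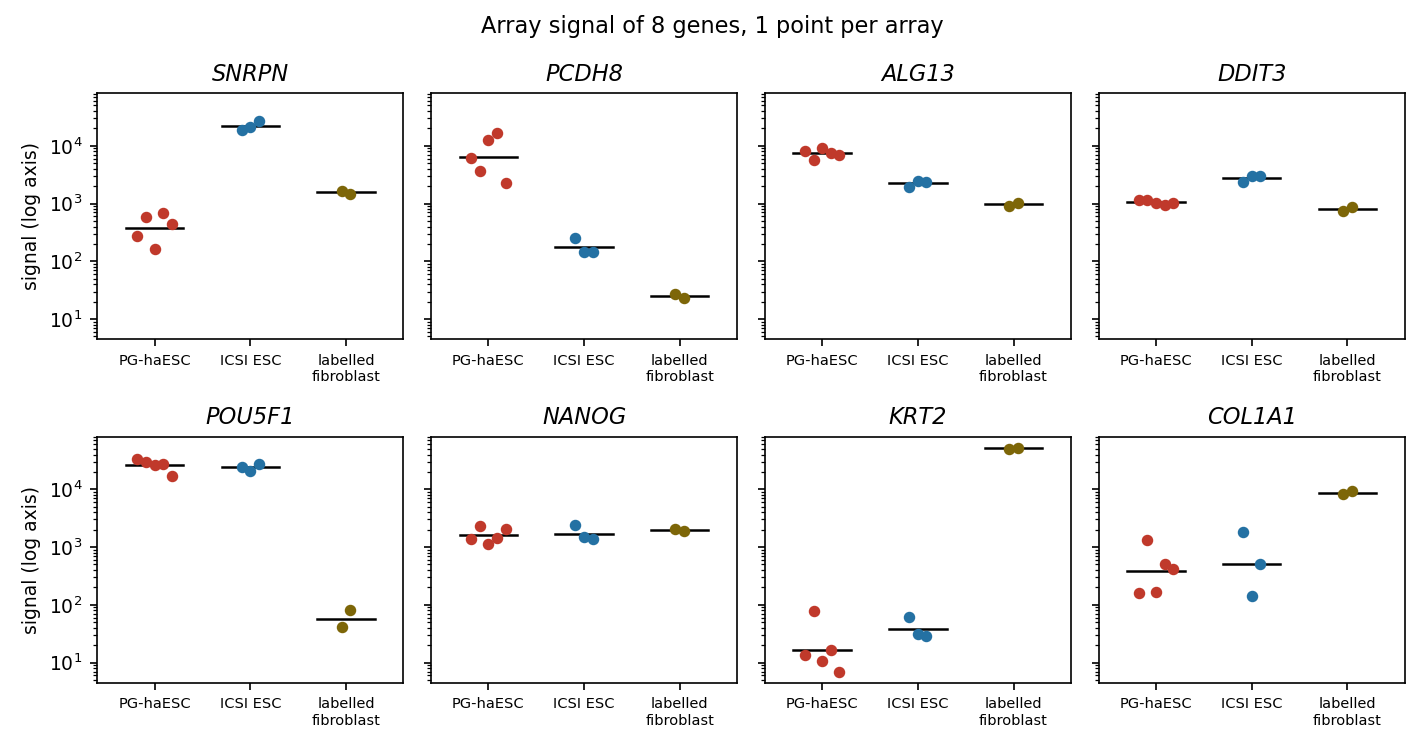
Deposited array signal (log axis, arbitrary units) of 8 genes, with 1 point per array and a line at the geometric mean, for PG-haESCs (5 arrays), ICSI ESCs (3 arrays) and arrays labelled fibroblast (2 arrays). SNRPN averages 380 in PG-haESCs against 21785 in ICSI ESCs, PCDH8 averages 6387 against 174, and KRT2 averages 50992 on the arrays labelled fibroblast.

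Of 380 X-linked genes measured, 36 rose in PG-haESCs against ICSI ESCs over all probe sets tested and none fell. The genes passing numbered 60, 8 or 2 without ICSI ESC array 1, 2 or 3, 8, 20, 6 or 15 without PG-haESC array 1, 2, 3 or 4, and 14 without either fibroblast array. None passed with arrays averaged per line, and 3 did when averaged per description code. With arrays centred on their medians 2 passed, without an intensity trend 1, and with arrays as independent samples 89. Adjusted over the list alone, 159 rose and 1 fell, TLR7 (log2 change -0.37 ± 0.13, and 0.02 with the mean of its probe sets), named here after its values were seen. The median log2 change was 0.67, or 1.59-fold (bootstrap 95% interval over genes 0.61 to 0.73 log2), and 87.6% of the genes had a change above 0. The medians of the 20 autosomes lay between -0.08 and 0.05. The list passed the test against genes placed on autosomes (camera, adjusted p = 2.8e-51, and 6.2e-27 with an estimated correlation), which does not measure the spread between lines. The X-linked genes with the smallest p were ALG13, the spermine synthase gene SMS (2.52-fold), the proton pump assembly gene VMA21 (2.01-fold) and MCTS1 (2.12-fold). VMA21 did not pass with the mean of its probe sets (log2 change 1.98, adjusted p = 0.20, and 0.0019 to 0.28 over all alternatives). Per array, the median X-linked level minus the median autosomal level was 0.45 ± 0.06 log2 in PG-haESCs (SD, n = 5), -0.20 ± 0.04 in ICSI ESCs (n = 3) and -0.30 ± 0.02 on the arrays labelled fibroblast (n = 2). All 5 PG-haESC arrays (0.38 to 0.53) lay above all 3 ICSI ESC arrays (exact two-sided permutation test over the 56 splits, p = 0.0179, the smallest they can give). This p takes arrays as exchangeable, although 4 of the 5 PG-haESC arrays are of line MPH1, so it does not measure the spread between lines. With arrays averaged per line, 2 lines against 3, the exact permutation p was 0.1, again the smallest possible, so that test could not reach 0.05.

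**Figure D2:**
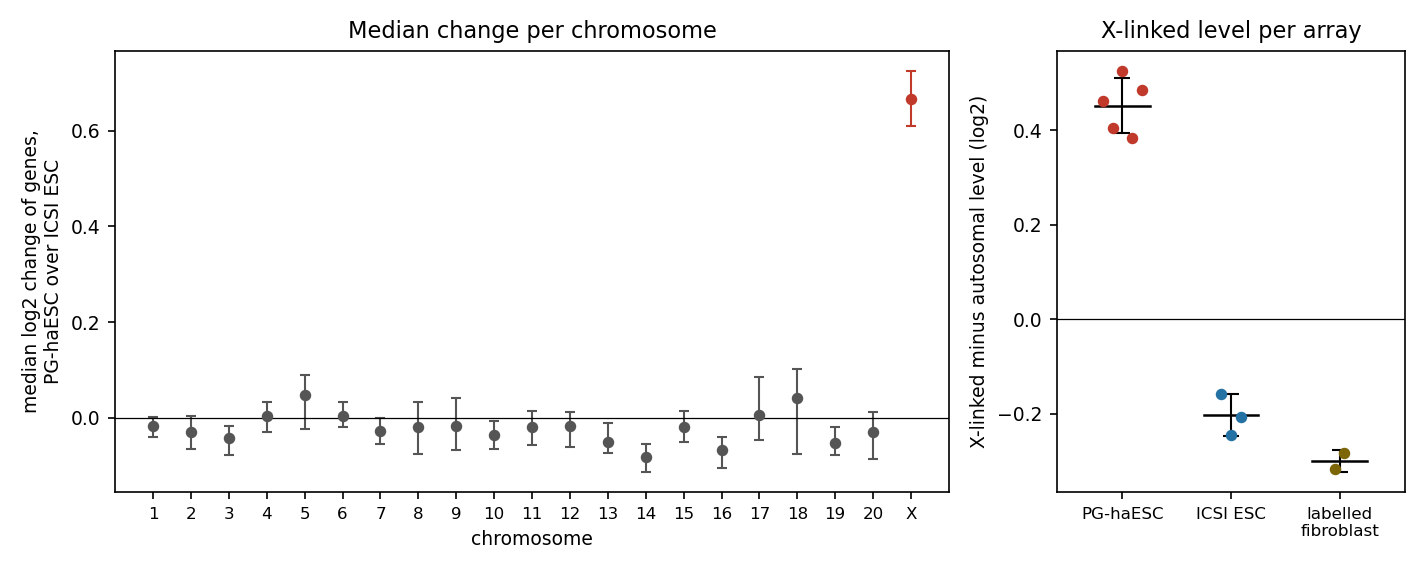
Left, the median log2 change of genes on each chromosome, PG-haESC over ICSI ESC, with bootstrap 95% intervals over genes. Right, the median X-linked minus the median autosomal log2 level of each array (points), with group mean and SD. Chromosome X lies at 0.67 and the autosomes between -0.08 and 0.05, and the 5 PG-haESC arrays lie between 0.38 and 0.53.

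Of 11 measured genes known as paternally expressed imprinted genes, SNRPN alone passed over all probe sets tested, and 2 were lower adjusted over the list alone. The list itself did not pass (median log2 change -0.25, adjusted p = 0.062). MAGEL2, from the same imprinted region in other mammals, had a log2 change of -2.31 (adjusted p = 0.21), and MEST, outside it, of -0.25 (adjusted p = 0.98). PEG3 had -1.31 (adjusted p = 0.97), with signals of 482 and 447 on ICSI ESC arrays 2 and 3 and 3.63 on ICSI ESC array 1. All 5 PG-haESC signals lay below their array medians. Without ICSI ESC array 1, PEG3 passed (adjusted p = 0.021, and 0.018 to 1.00 over all alternatives) and was at least 4.93-fold lower in PG-haESCs. NDN, another gene of the SNRPN region in other mammals, singled out after its values were seen, averaged 7490 in PG-haESCs and 7507 in ICSI ESCs (log2 change -0.01 ± 0.20). None of 12 maternally expressed imprinted genes passed (list adjusted p = 0.71), and 1 rose adjusted over the list alone. ZNF597 had a log2 change of 1.27 (adjusted p = 0.21) and H19 of 1.89 (adjusted p = 0.72), with 14625 on PG-haESC array 5 and 645 to 3432 on the other 4.

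Pluripotency genes did not separate PG-haESCs from ICSI ESCs. None of 19 core pluripotency genes passed (list median 0.18, adjusted p = 0.33). Log2 changes were 0.05 ± 0.28 for POU5F1, 0.43 ± 0.22 for SOX2, -0.03 ± 0.31 for NANOG and 0.51 ± 0.20 for the methyltransferase gene DNMT3B (SE). The NANOG probe set did not separate PG-haESCs (-0.26) or ICSI ESCs (-0.24) from the arrays labelled fibroblast either, so it tells little about pluripotency here. Endoderm genes were the second list to pass beside the X-linked genes, lower in PG-haESCs (median -0.89 over 15 genes, adjusted p = 0.0086), with none passing singly over all probe sets tested or adjusted over the list alone. This call was lost with an estimated correlation (adjusted p = 0.34), without PG-haESC array 5 (0.089) and without ICSI ESC array 2 (0.073), while its adjusted p ran down to 3.3e-05 over the alternatives and its median to -1.64 with the 75th percentile filter. CER1 (log2 change -3.36 ± 1.54), SOX17 (-2.91 ± 1.16) and FOXA1 (-2.06 ± 0.59) did not pass and varied within both groups. CER1 ran from 48.0 to 6310 over PG-haESC arrays and from 1867 to 7475 over ICSI ESC arrays. No other list passed, with adjusted p from 0.062 to 0.97, and among their members SNRPN alone passed over all probe sets tested. Without ICSI ESC array 1, 1 further member passed in each of 7 lists, and without PG-haESC array 2 in 1 list. The FGF-ERK feedback genes (adjusted p = 0.062, 2 lower adjusted over the list alone) included DUSP5 at -0.96 (adjusted p = 0.24) and SPRED2 at -0.70 (adjusted p = 0.30). The germ cell genes (adjusted p = 0.066, 1 higher adjusted over the list alone) included DAZL, which averaged 131 in PG-haESCs, up to 184 on array 3, and 13.8 in ICSI ESCs, where it lay below every array median (adjusted p = 0.27). LDHA of the glycolysis list (adjusted p = 0.33, 1 lower adjusted over the list alone) had -1.94 (adjusted p = 0.14) and passed without ICSI ESC array 1 (-2.68, adjusted p = 0.0042, and 0.0042 to 0.75 over all alternatives). BMP4 of the mesoderm list (adjusted p = 0.36, 1 higher adjusted over the list alone) had 1.27 (adjusted p = 0.063), and without ICSI ESC array 1 it passed (1.33, adjusted p = 0.040, and 0.023 to 0.40 over all alternatives). Adjusted over the list alone, 1 neuroectoderm gene, DCX (at least 3.38-fold, list adjusted p = 0.33), and 1 WNT target, RNF43 (0.89 log2, list adjusted p = 0.40), were higher. Fibroblast and feeder genes (median -0.21, adjusted p = 0.36) did not separate the groups, with COL1A1 at -0.40 ± 0.92, but their mean level differed between ESC arrays, from 9.55 to 12.3 log2, with the maximum on ICSI ESC array 1. That array lay close to the arrays labelled fibroblast, whose mean level was 12.6 log2. Medians and means differed in sign for the primed-state and WNT target lists. SRY, the 1 measured Y-linked gene, averaged 115.1 in PG-haESCs and 128 in ICSI ESCs, where array medians ran from 76.8 to 133. PG-haESCs were derived without a sperm genome and so without a Y chromosome. Their value is thus not expression of SRY, and a like value in ICSI ESCs is no sign of it.

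The comparison of PG-haESCs with the arrays labelled fibroblast set the haploid ESCs against differentiated cells. PG-haESCs had high signals of the pluripotency factors. POU5F1 averaged 26293 and was at least 227-fold higher, SOX2 at least 120-fold and the RNA-binding protein gene LIN28B at least 71.1-fold, with adjusted p from 3.9e-09 to 1.3e-08. A fold is given as a lower bound where every array of the dimmer group lay below its array's median, which then stands for that group. The arrays labelled fibroblast had high signals of genes of the outer skin: KRTDAP was at least 588-fold, KRT2 at least 541-fold, LORICRIN at least 451-fold, FLG2 at least 247-fold and the desmosome gene DSC1 at least 217-fold lower in PG-haESCs (adjusted p from 4.9e-07 to 9.9e-05). USP14 was at least 354-fold lower, on a probe set whose name marks it as open to cross-hybridisation, so its identity is uncertain, and all 5 of its tested probe sets were lower. A list of 33 other epidermal and hair follicle genes, written after these genes were seen, had 24 measured. Of these, 22 were lower in PG-haESCs (median log2 change -4.01). The filter favours such a fall, since a gene dim on all ESC arrays was kept only if high on both arrays labelled fibroblast. ARHGAP36 (at least 17.6-fold), PCDH8 (at least 55.2-fold) and the neural plate gene ZIC2 (at least 61.7-fold) were also higher, chosen by fitted fold, which is uncertain for signals below the array median.

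In all, 11275 probe sets differed between PG-haESCs and the arrays labelled fibroblast, 5796 higher and 5479 lower in PG-haESCs, 9707 of them by at least 2-fold. By gene, 2682 rose and 2009 fell. Of 19 core pluripotency genes, 14 rose and none fell (15 rose adjusted over the list alone; median log2 change 4.64, adjusted p = 2.1e-08), with DNMT3B at 5.51 ± 0.25 (SE). With signals below the array median set to it, the median was 3.02. NANOG did not pass (-0.26 ± 0.37, adjusted p = 0.65), with 1991 on the arrays labelled fibroblast and 1604 in PG-haESCs, and its sign turned when arrays were centred on their medians (0.15). Of 9 primed-state genes, 7 rose (adjusted p = 6.0e-05), among them the neural factor gene SOX11 (at least 32-fold) and CYTL1 (at least 16.5-fold). All 11 G2/M genes rose (adjusted p = 1.2e-09), with CCNB1 at 4.94, MAD2L1 at 4.67, CCNA2 at 4.0 and CENPF at 3.50 log2. Of 17 G1/S genes, 14 rose (adjusted p = 3.3e-09), with CCNE1 at 4.35, MCM3 at 3.56 and PCNA at 2.6. Oxidative phosphorylation genes had 12 of 22 higher (median 0.70, adjusted p = 0.0030), with COX5A at 1.75 and ATP5F1B at 1.21. Taking the mean of all probe sets of a gene ended this call (median 0.32, adjusted p = 0.081, and 0.00084 to 0.081 over all alternatives) and that of ATP5F1B. The 10 DNA methylation regulators had 6 higher and 3 lower (median 3.17, but 0.99 with no filter on dim probe sets, adjusted p = 0.022), with HELLS at 4.97, TET1 at 4.52 and DNMT3A at 4.41, and without ICSI ESC array 1 their adjusted p was 0.076 (0.0019 to 0.12 over all alternatives). Adjusted over the list alone, 15 G1/S and 14 oxidative phosphorylation genes were higher, and the counts of the other lists here were the same. Each of these lists but the methylation regulators also kept its call when any array was left out, and all of them kept it with an estimated correlation (adjusted p from 0.00014 to 0.044).

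Further lists moved between PG-haESCs and the arrays labelled fibroblast beside the epidermal genes (median -4.01). X-linked genes had 156 higher and 39 lower of 380 (161 and 47 adjusted over the list alone; median 0.75, adjusted p = 5.8e-05, and 0.0067 with an estimated correlation), with HMGB3 at 5.03 (2.89 with the mean of its probe sets) and TMSB15A at 4.97. FGF-ERK feedback genes had 6 of 10 higher and 1 lower (8 and 1 adjusted over the list alone; adjusted p = 0.012, and adjusted p = 0.067 with an estimated correlation), with ETV4 at 3.62. Glycolysis genes had 8 of 15 higher and 2 lower (adjusted p = 0.021, and adjusted p = 0.51 with an estimated correlation), and 10 were higher and 2 lower adjusted over the list alone, with SLC2A3, a glucose transporter gene, at 5.44 and GAPDH at 2.5. HOX genes, which pattern the body axis, had 5 of 16 lower (adjusted p = 0.014, and adjusted p = 0.51 with an estimated correlation), with HOXA9 at -4.98 and HOXA5 at -4.37 (-2.11 with passage as a covariate). Of 25 fibroblast and feeder genes 7 were lower and 3 higher (9 and 3 adjusted over the list alone; adjusted p = 0.022, and adjusted p = 0.77 with an estimated correlation), and 18 passed without ICSI ESC array 1. COL1A1 was at -4.49 ± 1.12 and FBLN1 at -3.14, while CCN2, a matricellular protein gene, was at 2.13 and the collagen gene COL5A2 at 1.81. The mean of all probe sets gave 0.59 for CCN2, which did not pass, and -0.23 for COL5A2. With passage as a covariate the fibroblast, HOX and glycolysis lists did not pass, and neither did COL1A1 (-2.07) or KLF4 (-1.57), but passage and these groups overlapped nowhere. Of the naive-state list, which did not pass (adjusted p = 0.69), KLF4 was at -3.78 and KLF5 at -3.19. Of the trophoblast list (adjusted p = 0.44), TP63, also a factor of the basal epidermis, was at -6.95 (-4.61 with the mean of its probe sets) and GATA3 at -4.79. SNRPN was lower in PG-haESCs (-2.01, adjusted p = 0.020; 0.071 without fibroblast array 1, and 0.0013 to 0.13 over all alternatives) and MEST higher (2.07, adjusted p = 0.0047; 0.050 with arrays averaged per line, and 1.1e-05 to 0.086 over all alternatives), while PEG3 (39.6 in PG-haESCs against 166, adjusted p = 0.40) and H19 (-0.23, adjusted p = 0.91, and 0.16 with arrays centred on their medians) did not pass. PEG3 passed without ICSI ESC array 1 (at least 1.77-fold lower, adjusted p = 0.022, and 0.016 to 0.60 over all alternatives). SRY passed the test (adjusted p = 0.028, and 0.0040 to 0.96 over all alternatives), but its signal on the arrays labelled fibroblast, 24.2, lay below their medians. With signals below the array median set to it the log2 change was -0.035, so no rise is reported. The lists not given here did not pass (adjusted p from 0.32 to 0.92), and medians and means differed in sign for the ribosomal proteins.

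Centring each array on its median moved the median log2 change of all probe sets from -0.09 to 0.33 between PG-haESCs and the arrays labelled fibroblast and from -0.06 to 0.36 between ICSI ESCs and those arrays. The share of calls that were higher rose from 51.4% to 68.7% and from 50.5% to 68.4%. Changes smaller than this shift have no settled direction. Averaging the arrays of each line lowered the number of calls between PG-haESCs and the arrays labelled fibroblast to 6294.

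**Figure D3:**
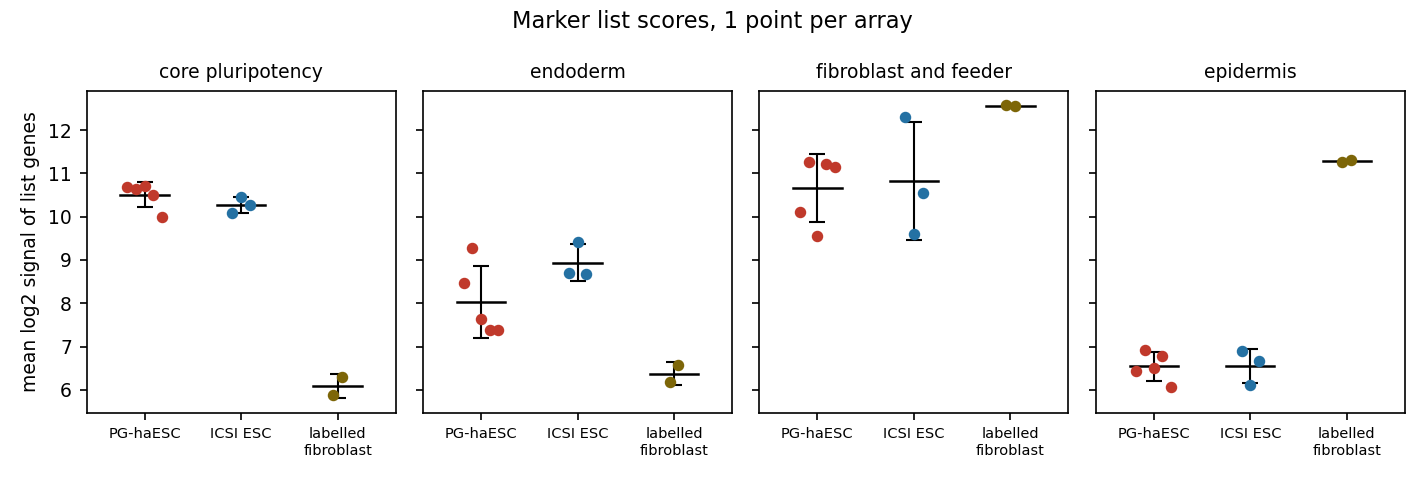
Mean log2 signal of the measured genes of 4 marker lists on each array (points), with group mean and SD, for PG-haESCs, ICSI ESCs and arrays labelled fibroblast. The core pluripotency score averages 10.5, 10.3 and 6.09 in these groups and the epidermal score 6.54, 6.55 and 11.3, while the fibroblast score of ESC arrays runs from 9.55 to 12.3. On the arrays labelled fibroblast the fibroblast score averages 12.6, close to the 12.3 of ICSI ESC array 1.

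The comparison of ICSI ESCs with the arrays labelled fibroblast gave the same contrast for diploid ESCs. POU5F1 averaged 23916 in ICSI ESCs and was at least 207-fold higher, ZIC2 at least 104-fold, SOX2 at least 87.0-fold, LOC699676 at least 75.3-fold, LIN28B at least 63.1-fold and ARHGAP36 at least 15.3-fold, with adjusted p from 6.9e-09 to 0.0011. Epidermal genes were lower in ICSI ESCs: KRTDAP at least 583-fold, FLG2 at least 245-fold and DSC1 at least 215-fold, with adjusted p up to 1.0e-04. LOC703076 (at least 268-fold), LOC697328 (at least 216-fold) and the uncertain USP14 probe set (at least 351-fold) were also lower, again chosen by fitted fold. Of the 24 measured genes of the added epidermal list, 20 were lower in ICSI ESCs (median -4.20), with the same limit of the filter. SNRPN was higher in ICSI ESCs (3.8 ± 0.60, adjusted p = 4.1e-04).

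In all, 11150 probe sets differed between ICSI ESCs and the arrays labelled fibroblast, 5633 higher and 5517 lower in ICSI ESCs, 9620 of them by at least 2-fold. By gene, 2625 rose and 1982 fell. Of 19 core pluripotency genes 14 rose (median log2 change 4.72, adjusted p = 6.1e-08), with DNMT3B at 5.0. With signals below the array median set to it, the median was 3.39. NANOG did not pass (-0.24 ± 0.37, adjusted p = 0.68), and its sign turned when arrays were centred on their medians (0.18). Primed-state genes had 7 of 9 higher (adjusted p = 6.1e-05), with SOX11 at least 24.6-fold and CYTL1 at least 19.9-fold. G2/M genes had 11 of 11 higher (adjusted p = 1.5e-09), with CCNB1 at 4.55 and MAD2L1 at 4.54, and G1/S genes 14 of 17 (adjusted p = 5.3e-09), with MCM10 at 4.34 and PCNA at 2.65. FGF-ERK feedback genes had 7 of 10 higher and 1 lower (9 and 1 adjusted over the list alone; adjusted p = 0.0026), with the growth factor gene FGF2 at least 8.82-fold and SPRY4 at least 9.82-fold. Oxidative phosphorylation genes had 13 of 22 higher (adjusted p = 0.0028, but 0.061 with the mean of all probe sets of a gene, and 0.00085 to 0.061 over all alternatives), with COX5A at 1.62, which did not pass with that mean (0.40, adjusted p = 0.35, and 1.1e-05 to 0.35 over all alternatives). DNA methylation regulators had 6 of 10 higher and 3 lower (median 3.11, but 1.06 with no filter on dim probe sets, adjusted p = 0.030, but 0.063 without ICSI ESC array 1, and 0.0022 to 0.093 over all alternatives), with HELLS at 5.10. Adjusted over the list alone, the counts of the other lists in this paragraph were the same. These calls held with an estimated correlation (adjusted p from 1.1e-04 to 0.042).

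Endoderm genes had 8 of 15 higher and 1 lower in ICSI ESCs than on the arrays labelled fibroblast (median 2.47, adjusted p = 0.032, and adjusted p = 0.44 with an estimated correlation, 0.0039 to 0.44 over all alternatives), with LAMA1 at least 9.93-fold, FOXA2 at least 5.72-fold and APOA1 at least 4.02-fold. Without fibroblast array 1, 5 endoderm genes passed in all, against 9 with it. Glycolysis genes had 9 of 15 higher and 1 lower (9 and 2 adjusted over the list alone; adjusted p = 0.0099, and adjusted p = 0.44 with an estimated correlation), with SLC2A3 at 5.68. HOX genes had 6 of 16 lower (adjusted p = 0.0099, and adjusted p = 0.44 with an estimated correlation), with HOXA9 at -5.47, and 3 or 2 passed without fibroblast array 1 or 2. Beside these lists the added epidermal list had a median of -4.20. The fibroblast and feeder list did not pass (8 of 25 lower and 3 higher, 17 in all without ICSI ESC array 1 and 6 without fibroblast array 2, adjusted p = 0.062), with COL1A1 at -4.09 ± 1.13 (adjusted p = 0.015, but 0.054 without fibroblast array 2, and 0.00047 to 0.37 over all alternatives) and FBLN1 at -2.68 (-1.60 with the mean of its probe sets). Of the trophoblast list (adjusted p = 0.37) TP63 was at -7.75, and of the naive-state list (adjusted p = 0.68) KLF4 was at -3.42. With passage as a covariate KLF4 (-1.03, adjusted p = 0.20, and 3.1e-05 to 0.20 over all alternatives), COL1A1 (-1.45) and the HOX and glycolysis lists did not pass. X-linked genes did not pass (median 0.14, adjusted p = 0.85), with 87 higher and 70 lower (92 and 78 adjusted over the list alone), among them SLC7A3 (at least 43.5-fold higher) and XG (at least 139-fold lower). MEST was higher (2.32, adjusted p = 0.0024; 0.061 with passage as a covariate, and 4.5e-06 to 0.061 over all alternatives), while H19 (-2.12, adjusted p = 0.17) and PEG3 (-0.85, adjusted p = 0.77) did not pass. SRY passed the test (adjusted p = 0.015, and 0.0035 to 0.85 over all alternatives) against signals below the array median, and with those set to the median the log2 change was 0.15, so no rise is reported. The lists not given here did not pass (adjusted p from 0.14 to 0.91), and medians and means differed in sign for the paternally expressed imprinted genes and the ribosomal proteins. The ratio of 3' to 5' control signals, a sign of RNA quality, was higher on the arrays labelled fibroblast in both fibroblast comparisons, untested. For GAPDH it was 3.85 ± 0.31 (SD, n = 2) against 2.04 ± 0.24 in PG-haESCs (n = 5) and 1.93 ± 0.10 in ICSI ESCs (n = 3). For actin it was 8.77 ± 0.53 against 3.86 ± 0.93 and 3.63 ± 1.76 in the same order. The actin ratio also varied among ESC arrays, from 2.30 on ICSI ESC array 2 to 5.62 on ICSI ESC array 1.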

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

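Tests chosen only after the result was seen were those of signal level, X dosage, parthenogenetic origin, exchange with an ESC array, keratin cross-hybridisation, carry-over of RNA and fibroblast-like cells, while the splits of the samples, RNA from skin and array scaling were set before.

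Of 104 values tested within the 5 PG-haESC arrays, 8 had an array far from the others. Chance gives about 1 in 20 for independent arrays and values. That rate does not apply here, since array 5 alone is of line MPH2, the others are of MPH1, and the values are related. An outlying array 5 cannot be told apart from a difference between the lines. The gap to the nearest other array as a share of the range (critical value 0.71) was 0.855 for ABCA8, 0.712 for SEPTIN6, 0.723 for SLC2A3 and 0.819 for KLF5 on PG-haESC array 2. It was 0.779 for ARHGAP36, 0.801 for COX5A and 0.712 for the core pluripotency score on PG-haESC array 5, and 0.715 for the GAPDH 3' to 5' ratio on PG-haESC array 1.

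Among the 56 splits of the 8 ESC arrays into 5 and 3, only the real split, 1 of 56, gave as many called probe sets (183 with a correlation estimated on a subset of probe sets, highest other 35, 49 splits with 0). Chance is not excluded by this, since 4 of the 5 PG-haESC arrays are of 1 line and arrays of a line are not exchangeable. The splits that keep that line together number 4, too few for a share under 0.05 (real 183, highest other 0).

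X-linked genes were higher in PG-haESCs by a median of 0.67 log2. Signal level does not account for it, since the X-linked median lay above 100% of 10000 autosomal lists matched on mean signal (highest 0.07). X to autosome dosage stays open, and its prediction was met. Every PG-haESC array lay above every diploid array, by 0.54 log2 at the nearest, and the diploid groups differed by 0.10. The first of these restates the rise that prompted the test, so it adds no support for dosage. A doubling would give 1 log2, more than the median seen, and this test set no size. Parthenogenetic origin apart from ploidy cannot be told apart from dosage, as 0 diploid parthenogenetic arrays were in the series.

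Epidermal genes were high on the arrays labelled fibroblast. The highest ESC array median of the epidermal list was 123, against 1655 and 1796 on the arrays labelled fibroblast, so no ESC array had high epidermal signals. This restates the pattern and does not decide on an exchange with an ESC array. The genes that prompted the list were chosen with all ESC arrays lower. Keratin cross-hybridisation is argued against by a median of 3.75 log2 (interval 3.34 to 6.12) over 17 epidermal genes other than keratins. RNA from skin, rather than from fibroblasts alone, stays open as a hypothesis. Of 4 lists of other skin cell types, 3 were higher on the arrays labelled fibroblast than in ICSI ESCs by a median above 1 log2. The filter leaned towards this result and towards the epidermal medians. A gene dim on all ESC arrays was tested only if it lay above the median on both arrays labelled fibroblast. From the arrays labelled fibroblast to ICSI ESCs the medians fell by 2.02 (melanocyte), fell by 3.78 (endothelial) and fell by 4.86 (leukocyte), and the adipocyte median was -0.08. Cultured cells of another kind and a wrong label with a sample outside the series were not tested.

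Fibroblast genes differed between ESC arrays, with DCN from 182 to 39481 and LUM from 137 to 9249, genes named after their values were seen. Array scaling is argued against, since the spread after quantile normalization was 0.937 of that before. RNA carried over from the sample of the arrays labelled fibroblast is argued against by the epidermal list's share over the fibroblast list's share on ICSI ESC array 1, 0.0557 (interval 0.0066 to 0.139, shares 0.0332 and 0.596), although the bound of this test was rewritten after its value was seen, an earlier bound lying inside the interval. RNA of fibroblast-like cells, feeder or differentiated, stays open: the list's genes had a mean correlation of 0.479 over the 8 ESC arrays, but the spread of the list's mean alone requires about 0.528, so this test decides nothing. No other biological explanation was tested for this pattern.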

How the results depend on the processing

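Tests chosen after the result was seen were those without the 2 arrays of highest spike-in signals, with dim signals set to the array median and with the fibroblast score as a covariate. The 154 calls between PG-haESCs and ICSI ESCs became 475 with arrays as independent samples, 256 with description code as the block, and 9 and 20 with arrays averaged per line or code. They became 295 with only those groups, 30 with arrays centred on their medians and 102 with the 75th percentile filter. They became 13 without an intensity trend, 287 with passage as a covariate and 441 without the spike-in arrays. Leaving out an array gave 8 to 395. Between PG-haESCs and the arrays labelled fibroblast, 11275 became 6294 with arrays averaged per line, and 8262 to 14046 without 1 array. The 11150 calls between ICSI ESCs and those arrays stayed within 1.5 times under every alternative (8045 to 12687 without 1 array). Where an arm had 1 array left, it was assumed to vary like the other groups. Of 24 gene lists, 2 passed between PG-haESCs and ICSI ESCs; 4 did with arrays averaged per line or code, an offset, no filter, without the spike-in arrays or with dim signals at the array median, 5 with quantile normalization, centring or the mean of probe sets, 1 with an estimated correlation, and 1 to 4 without 1 array. The median r between PG-haESCs and ICSI ESCs, 0.893, was 0.871 with no filter and 0.916 with the 75th percentile filter. Signs turned between PG-haESCs and ICSI ESCs for genes that had not passed: NANOG (averaged per line 0.054, without the spike-in arrays 0.10, fibroblast score 0.0025, without 1 array -0.19 to 0.21), POU5F1 (averaged per line -0.091, without 1 array -0.048 to 0.29), COL1A1 (without the spike-in arrays 0.11, without 1 array -1.32 to 0.51), NDN (quantile 0.0010, passage 0.017, without the spike-in arrays 0.0091, without 1 array -0.087 to 0.075), TLR7 (mean of probe sets 0.021), SRY (without 1 array -0.52 to 0.070) and MEST (without 1 array -0.78 to 0.035). Against the arrays labelled fibroblast, signs turned in PG-haESCs for H19 (averaged per line 0.38, centred 0.16, mean of probe sets 0.31, without 1 array -1.28 to 0.17), NANOG (centred 0.15, passage 0.32), COL5A2 (mean of probe sets -0.23) and SRY (dim signals at the array median -0.035), and in ICSI ESCs for NANOG (centred 0.18, passage 0.40) and PEG3 (offset 0.055, without the spike-in arrays 1.48, dim signals at the array median 0.82, without 1 array -2.05 to 1.48). For these, the cause was not tested. Among named genes, 21 of 48 passed between PG-haESCs and ICSI ESCs and 1 kept its call under all alternatives; 37 of 45 and 32 of 37 did in the fibroblast comparisons. The X-linked list passed under all 28 alternatives (median 0.59 to 0.72). The mean of probe sets gives no count of probe sets, the fibroblast score covers only the ESC arrays, and the 75th percentile filter left too few germ cell genes for a list test. No paired analysis was possible because replicate numbers only name the arrays of a group and link no sample of 1 group to 1 of another. Without detection calls, changes among dim signals are limited by background.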

Other observations

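The test of ATF4 targets was set before its list was run, on a list of genes written after DDIT3, DDIT4 and CHAC1 were seen, and its criterion was coded after the list's median but before its p was known.

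Signals of CER1, GSC and TBXT, genes expressed in the early embryo, varied between arrays of a group. CER1 was 1573, 6310, 268, 95.8 and 48.0 on PG-haESC arrays 1 to 5 and 2129, 7475 and 1867 on ICSI ESC arrays 1 to 3. The organiser gene GSC was 1102, 2831, 262, 110 and 94.8 against 2103, 5070 and 1273. TBXT, the mesoderm factor brachyury, was 116, 584, 115.2, 27.1 and 14.8 against 365, 518 and 808. Neither GSC (log2 change -2.93, adjusted p = 0.56) nor TBXT (-3.11, adjusted p = 0.48) passed between the groups.

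DDIT3, DDIT4 and CHAC1, which fell in PG-haESCs, are targets of the stress-response factor ATF4, and lower expression of ATF4 targets as a group may be present as a hypothesis. Of 27 other target genes 18 were measured and 17 had a change below 0 (median log2 change -0.22), none passing singly in limma, and the list test gave p = 0.00014 (0.0149 with an estimated correlation). The cause of such a shift was not tested. The p of this list sets genes against other genes and does not measure the spread between lines. Apart from the estimated correlation, the list was not tested under the alternatives.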
